A study of Rattus norvegicus with 40 samples.

How the data were processed

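Small RNA levels were measured on 40 one-colour Agilent arrays carrying probes for rat miRNAs. The RNA came from CG4-EPOR cells, a rat glial precursor line whose name marks it as carrying the erythropoietin (EPO) receptor. Per the labels' protocols, cells were kept undifferentiated with growth factors and conditioned medium, then moved to a differentiation medium with or without EPO and leukemia inhibitory factor (LIF), and total RNA was taken up in QIAzol, purified with miRNeasy columns and labelled with Cy3. The cells were collected undifferentiated (3 arrays) or after 1 h or 20 h in the differentiation medium. The 5 conditions at each time were control (4 arrays at each time), EPO at 10 ng/ml (4 at each time), LIF at 0.2 ng/ml, called LIFlow here (3 at each time), LIF at 10 ng/ml (4 at 1 h and 3 at 20 h), and EPO with LIF at 10 ng/ml each, called EPO+LIF (4 at each time). The labels do not say whether replicates were separate cultures, so the p-values measure only the spread between these samples.

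The deposited scanner files hold spot intensity values made with Agilent Feature Extraction 10.7.3.1, per the file headers, which also name the rat genome build rn4. Their processed signal is an intensity from which the scanner software had removed background, and the files mark outlier spots, saturated spots and spots well above background. The authors' deposited table holds log2 values. Set against the scanner files, each of its columns equalled log2 of the scanner software's total miRNA signal minus 1 constant per array, between 5.20 and 6.51, with a largest deviation of 1.08e-05. The origin of these constants is not stated; the table showed no centring of probes, and its column medians lay between -9.83 and -8.52. The total signal was 0.1 in 71.6% of values.

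Each array held 12843 spots, of which 715 were controls and were left out. The remaining 12128 spots belonged to 1806 probes. Outlier spots were also left out, between 7.62% and 9.76% of spots per array, and 0 spots were saturated. The processed signal was averaged over the spots of each probe. A probe counted as detected on an array when at least 50% of its spots were well above background, and a miRNA when any of its probes was. Each array was divided by its 75th percentile over the 244 probes detected on all arrays, probes of 1 miRNA were averaged, values under a floor were set to it, and log2 was taken. The floor was the 5th percentile of detected scaled probe values, 0.0384 or -4.70 on the log2 scale. Values at the floor have no order among themselves. The 192 miRNAs detected on all arrays of at least 1 group were tested. Where a miRNA was not well above background on any array of a group, the text gives a bound, written as at least so many fold. This bound sets the brighter group's mean against the mean, per array of the other group, of the higher of the array's lowest detected signal and the miRNA's own value, which is never under the floor. The lowest detected signals lay between -5.46 and -3.83. Positions of miRNAs are those in the scanner files. Among the called values of named miRNAs with more than 1 probe, 140 in number, 0 had probes that moved in opposite directions. A probe whose own difference was 0 could not count as opposite, and such calls rest on the other probes. Among them were miR-34a-5p with EPO at 20 h (0 and 0.75), miR-455-3p with LIFlow at 20 h (0 and 0.94) and miR-7a-5p in control 20 h against undifferentiated cells (-1.89 and 0). The calls of miR-351-5p also included such a probe.

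On each array between 154 and 212 miRNAs were detected (median 185), and between 16.7% and 23.4% of spots were well above background. The number of arrays per group limits the precision.

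The 11 group means were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with no block, and 23 comparisons were taken from this fit. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. Errors of log2 fold changes are standard errors. The 12 fixed lists were oligodendrocyte differentiation, against oligodendrocyte differentiation, the miR-17 clusters, the let-7, miR-29, miR-30 and miR-181 families, rapidly induced, STAT3-linked, erythroid and EPO-linked, hypoxia and p53, and the Dlk1-Dio3 imprinted cluster. A further 6 lists held miRNAs typical of other cell types: neuron, astrocyte, microglia and blood, muscle, endothelium and fibroblast, and epithelium. Lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01 and with an estimated correlation, and adjusted over the lists within a comparison. In 76 of 299 list tests the median, the mean and the direction of the test did not all have the same sign, and 0 of these passed the threshold.

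For each comparison the text names up to 10 miRNAs with the largest rise and up to 10 with the largest fall among those that passed the test and were detected on all arrays of at least 1 compared group. It also takes 9 miRNAs whatever their result (miR-219a-5p, miR-219a-2-3p, miR-338-3p, miR-17-5p, miR-9a-5p, miR-21-5p, miR-132-3p, miR-212-3p and miR-146a-5p) where tested, up to 4 members of each described list with the largest change, and the 5 lowest p-values where fewer than 5 miRNAs passed. Both arms of miR-351 in control 20 h against control 1 h, and miR-351-5p against undifferentiated cells, are named outside this rule and count among the named calls. Values that add nothing to the text are summarised. The comparisons, the design, the lists, the rule for named miRNAs and the other settings named next were chosen before the data were examined.

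These other settings were normexp background correction with an offset of 50, the percentile over all probes, quantile normalization, a test of every rat miRNA on the array or only of those detected on all 40 arrays, the scanner software's total signal, a floor at 50% of its value, the authors' table, blocks by slide, by title letter or by replicate number, and the omission of each array in turn. After seeing the data, 3 settings were added: slide together with the row of the array on its slide, the omission of slides 2 and 4, and the brightness of the array (log2 of its 75th percentile) as a covariate. Each of the 5 slides held 8 arrays and was scanned as 1 batch. Slides 1, 2 and 3 held the arrays with letters A, B and C of 8 groups, with the 1 h groups in row 1 and the 20 h groups in row 2. The other slides held the D arrays, the LIFlow groups and the undifferentiated cells. Because slides hold several groups, the text gives counts with slide as a block and the lead values within each slide.

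Whether letters pair the samples was checked from the correlation of same-letter arrays' deviations from their group means, with every pair over 0.1 and at least 3 pairs required. They did for control 20 h against control 1 h (0.105 to 0.637), for EPO, LIF and EPO+LIF against control at 1 h, for LIFlow and LIF against control at 20 h, and for EPO+LIF against LIF and against EPO at both times. Where letters pair samples they mostly share a slide. The B and C arrays of LIFlow at 20 h sat on other slides than their controls, but on slides of like brightness (4 and 2, 5 and 3). The check therefore cannot tell letters from slide brightness.

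The fit was tested on simulated data with 60 of 192 miRNAs changed in each of 20 runs. The changed miRNAs were drawn only from those with a mean well above the floor, and the simulated values had no floor. The shares of changes called therefore say nothing about miRNAs near the floor. For control 20 h against control 1 h, 46% of changes of 0.25 log2, 86% of 0.5 and 97.8% of 1 were called without a block, and 92.5%, 97.3% and 100.0% with slide as a block. For LIF against control at 20 h the shares were 33.3%, 82.5% and 98.5% without a block, and 90.5%, 98.3% and 99.8% with it. Of unchanged miRNAs, 0.303% and 0.379% were called without a block, and 1.89% and 1.70% with it. A shift of -0.2 in a list of 14 was found in 20 of 20 runs for each of these comparisons (camera at the preset correlation, unadjusted p under 0.05). Apart from slide effects, the noise was drawn independently for each miRNA, and no unshifted list was run. This result therefore does not show how the list tests fare where members vary together. The R packages data.table, version 1.17.8, and statmod 1.5.0 were also used.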

Results

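The series measured miRNAs in rat CG4-EPOR cells, a glial precursor line that can be turned towards oligodendrocytes, the myelin-forming cells of the central nervous system. It covered undifferentiated cells and cells held for 1 h or 20 h in differentiation medium as untreated controls or with the cytokines EPO, LIF or both. The 40 arrays fell into 11 groups of 3 or 4. Of the rat miRNAs on the array, 147 were detected on all 40 arrays and 525 on none, and 192 were tested. Group means of detected miRNAs per array lay between 169 and 201. Replicates of a group correlated at 0.976 to 0.9995 over miRNAs. Values are log2 of the scaled signal, given as mean ± SD, and log2 fold changes carry their standard error and a limma adjusted p. The floor of the scale was -4.70, and differences from values at the floor depend on where it lies. Their p-values depend on it too, since the fit pools the spread over all 11 groups. A group with every array at the floor adds no spread, so such p-values can be too small. Arrays hybridised on the same slide deviated together, so each count is followed by the count with slide as a block. Every miRNA called without a block was also called with the slide block, in the same direction.

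Control cells at 20 h were compared with control cells at 1 h to see what time in differentiation medium changed without added cytokine. The largest rise was that of miR-210-3p, a miRNA induced by low oxygen through hypoxia-inducible factors. It was not well above background on any of the 4 arrays at 1 h and reached -1.03 ± 0.19 (SD, n = 4) at 20 h, at least 9.88-fold higher (adjusted p = 1.35e-19). miR-338-3p, which is enriched in oligodendrocytes and promotes their differentiation, rose 1.91-fold from -1.29 ± 0.25 to -0.36 ± 0.13 (n = 4 each; log2 fold change 0.93 ± 0.14, adjusted p = 2.06e-06). miR-138-5p, another miRNA of differentiating oligodendrocytes, rose 2.45-fold (1.29 ± 0.13, adjusted p = 5.37e-09), and both arms of miR-140 rose, with 1.28 ± 0.11 for miR-140-3p (adjusted p = 7.7e-11) and 1.18 ± 0.14 for miR-140-5p (adjusted p = 4.11e-08). miR-503-5p showed the largest fall, from -0.28 ± 0.18 to -1.80 ± 0.15, 2.87-fold lower (-1.52 ± 0.11, adjusted p = 3.38e-12).

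Among the other rises from 1 h to 20 h were miR-101b-3p (0.77), miR-27b-3p (0.54), miR-23b-3p (0.51), miR-598-3p (0.45) and miR-17-5p (0.44 ± 0.12, adjusted p = 0.00461). miR-17-5p belongs to a cluster known to drive cell proliferation. The falls included miR-672-5p (-0.91), miR-3544 (-0.88), miR-99a-5p (-0.69), miR-25-3p (-0.68) and miR-15b-5p (-0.64). The neighbours of miR-503-5p on the X chromosome also fell, with -0.64 for miR-322-5p and -0.62 for miR-351-5p, and miR-351-3p was undetected at 20 h and at least 1.31-fold lower. miR-212-3p fell by 0.25 (adjusted p = 0.0308). Values that did not pass were 0.05 for miR-219a-5p, a promoter of oligodendrocyte differentiation, -0.12 for miR-9a-5p and -0.04 for miR-21-5p. miR-132-3p lay at the floor on every array of both groups, so that no difference was measurable, while miR-219a-2-3p and miR-146a-5p were not detected widely enough to be tested. Every other array also had miR-132-3p at the floor. At 20 h it was nevertheless detected on all LIFlow, LIF and EPO+LIF arrays, against 2 of 4 with EPO and 1 of 4 controls, which was not tested. In all, 26 miRNAs rose and 34 fell, and with slide as a block 44 rose and 59 fell. The balance turned with the scaling, with 29 rises and 16 falls over all probes, 28 and 25 after quantile normalization and 19 and 64 in the authors' values. Within the 3 slides shared by both groups, miR-210-3p was at least 10.4-fold higher, and the difference was 0.86 to 1.09 for miR-338-3p, 1.08 to 1.33 for miR-138-5p and -1.52 to -1.38 for miR-503-5p. Of 32 named calls, 24 passed without each array in turn, and those that ended included miR-98-5p (adjusted p = 0.147 without control 1 h replicate 4), miR-30a-5p (0.209 without the same array) and miR-146b-5p (0.155 without control 1 h replicate 2). Among the falls given above, miR-3544 (0.115 without control 1 h replicate 3) and miR-212-3p (0.103 without control 1 h replicate 1) ended too. miR-30a-5p, 0.08 here, was -0.03 in the authors' values.

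The fixed lists were set against the same comparison. In the oligodendrocyte differentiation list, 2 of 4 tested members rose, also 2 adjusted over the list alone, and all 4 were higher (median 0.51, adjusted p = 0.0354). That call ended with an adjusted p = 0.103 with an estimated correlation, with slide as a block (0.0707), and without control 1 h replicate 2 (0.0656), control 1 h replicate 4 (0.0602) or control 20 h replicate 2 (0.0574). It also ended with normexp correction (median 0.02, 0.149), among miRNAs detected on all arrays (median 0.08, 0.439), with every miRNA tested (median 0.00, 0.133), with quantile normalization (0.0634), in the total signal (0.154) and in the authors' values (0.153). The same held for slide and row as blocks (0.0593), array brightness (0.360) and the fit without slides 2 and 4 (0.190). The hypoxia and p53 list also passed, with 2 of 5 risen, miR-210-3p among them, and also 2 adjusted over the list alone (median 0.20, adjusted p = 0.0354); the adjusted p was 0.497 with an estimated correlation and 0.0707 with slide as a block. It was 0.0660 without control 1 h replicate 1 (median 0.13), 0.0520 without control 1 h replicate 2 and 0.0825 without control 20 h replicate 2, and with normexp correction the median turned to -0.18 (0.329). It was 0.133 with every miRNA tested (median 0.04), 0.0579 with slide and row as blocks and 0.190 without slides 2 and 4. Of 5 miRNAs acting against oligodendrocyte differentiation 2 fell, miR-9a-3p (-0.39) and miR-212-3p (-0.25), also 2 adjusted over the list alone (median -0.12, adjusted p = 0.704). The 14 tested members of the miR-17 clusters went both ways, with 3 risen and 3 fallen, 4 and 3 adjusted over the list alone, a median of 0.14 and an adjusted p of 0.735. In the miR-30 family 2 of 5 rose, 3 adjusted over the list alone (median 0.19, adjusted p = 0.284). The let-7 family had 1 of 9 risen and 0 adjusted over the list alone (median 0.00, adjusted p = 0.818), and the miR-181 family 1 of 4 risen, also 1 adjusted over the list alone (median 0.07, adjusted p = 0.704). In the miR-29 family 0 of 3 passed (median -0.06, adjusted p = 0.869), as in the Dlk1-Dio3 imprinted cluster (median -0.24, adjusted p = 0.818). Of 4 rapidly induced miRNAs, miR-132-3p at the floor among them, 1 fell (median -0.02, adjusted p = 0.905). In the STAT3-linked list 1 rose and 1 fell of 6 (median 0.02, adjusted p = 0.818), and in the erythroid and EPO-linked list 1 rose and 1 fell of 4 (median -0.03, mean 0.74, adjusted p = 0.477). For these last 3 lists the counts adjusted over the list alone were the same.

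Against undifferentiated cells, control cells at 20 h showed the sum of leaving the growth medium and of time in differentiation medium. miR-210-3p, undetected in all 3 undifferentiated samples, was at least 10.1-fold higher (adjusted p = 1.21e-18). miR-338-3p rose 1.84-fold from -1.24 ± 0.26 (n = 3) to -0.36 ± 0.13 (n = 4; 0.88 ± 0.15, adjusted p = 1.9e-05). Rises were also found for miR-140-3p (1.25 ± 0.12), miR-138-5p (1.20), miR-140-5p (1.10), miR-101b-3p (0.62), miR-23b-3p (0.59) and miR-17-5p (0.49). miR-503-5p fell 2.51-fold (-1.33 ± 0.12, adjusted p = 4.4e-10), and miR-7a-5p fell by at least 1.03 (adjusted p = 5.83e-05) to the floor on all 4 control arrays, 2 of which still detected it. Further falls were miR-672-5p (-0.90), miR-25-3p (-0.69), miR-199a-3p (-0.68), miR-9a-3p (-0.56), miR-322-5p (-0.54) and miR-351-5p (-0.54). In total 22 miRNAs rose and 23 fell, and with slide as a block 40 rose and 38 fell, while scaling over all probes gave 11 and 22 and the authors' values 13 and 65. Only slide 5 held both groups, with miR-210-3p at least 9.50-fold higher and differences of 1.00 for miR-338-3p and -1.32 for miR-503-5p. Without undifferentiated replicate 1 the calls of miR-1224 (adjusted p = 0.105), miR-29b-3p (0.192), miR-30e-5p (0.150) and miR-129-2-3p (0.150) ended, without replicate 2 that of miR-34c-5p (0.178) and without replicate 3 that of miR-494-3p (0.0588); miR-181a-5p, 0.21 here, was -0.00 in the authors' values.

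After only 1 h in differentiation medium, control cells differed little from undifferentiated cells. miR-351-3p, undetected in the undifferentiated cells, was at least 1.08-fold higher (adjusted p = 0.00442), miR-466b-3p rose by a fitted 0.48 ± 0.11 (with 2 of 3 undifferentiated arrays at the floor, adjusted p = 0.0119) and miR-384-5p by 0.17 ± 0.04 (adjusted p = 0.031). miR-199a-3p fell by 0.17 (adjusted p = 0.036). miR-21-5p stood at -0.21 (adjusted p = 0.336). These were 3 rises and 1 fall, against 12 and 11 with slide as a block. Their direction was not settled, with 0 rises and 3 falls over all probes, 2 and 3 after quantile normalization and 0 and 12 in the authors' values. Without undifferentiated replicate 1 only 1 call was left, with adjusted p of 0.181 for miR-199a-3p and 0.0712 for miR-466b-3p, whereas 9 were made without control 1 h replicate 2; miR-384-5p was -0.03 when arrays were scaled over all probes.

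The next comparisons asked what each cytokine had changed against untreated cells after 1 h. EPO, the growth factor of red cell precursors, gave 0 calls by limma, with 4 miRNAs at an unadjusted p under 0.05, 1 call with slide as a block and 1 without control 1 h replicate 2. The lowest p-values belonged to miR-466b-3p (-0.31, adjusted p = 0.455) and to the brain-enriched miR-129-2-3p, with -0.20 and an adjusted p of 0.455, or 0.0459 with slide as a block. The 14 members of the miR-17 clusters had a median of 0.04, with 11 higher and 0 called (adjusted p = 0.0111), and 0 were called adjusted over the list alone; the adjusted p was 0.0529 with an estimated correlation. This list had no settled direction, since its median was -0.00 without EPO 1 h replicate 1 (adjusted p = 0.287), 0.00 without control 1 h replicate 4 (0.597), 0.01 without control 1 h replicate 3 (0.0625), 0.02 without EPO 1 h replicate 2 and -0.02 with normexp correction. It was 0.12 over all probes, 0.11 in the total signal, 0.09 in the authors' values and 0.07 without slides 2 and 4, and the call ended with quantile normalization (0.0575) and with every miRNA tested (0.195).

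LIFlow for 1 h raised miR-872-5p by 0.21 ± 0.05 (adjusted p = 0.0434). It lowered miR-129-2-3p from -2.66 ± 0.16 (n = 4) to -3.00 ± 0.04 (n = 3; -0.34 ± 0.07, adjusted p = 0.00871) and miR-466b-3p to below detection on all 3 arrays, at least 1.12-fold lower (adjusted p = 0.00871). These 3 calls became 4 rises and 10 falls with slide as a block, and 3 rises and 0 falls over all probes and in the authors' values. On the 1 shared slide miR-129-2-3p was -0.31 and miR-466b-3p at least 1.15-fold lower. Without control 1 h replicate 2 there were 7 calls, while miR-872-5p reached an adjusted p of 0.266 without LIFlow 1 h replicate 2; with normexp background correction miR-129-2-3p was 0.32 and miR-466b-3p 0.50.

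LIF at 10 ng/ml for 1 h raised miR-351-3p 1.87-fold, from -4.26 ± 0.20 to -3.35 ± 0.18 (n = 4 each; 0.90 ± 0.08, adjusted p = 1.19e-09). It was detected on 4 of 4 LIF arrays and 2 of 4 control arrays, and was 0.55 to 1.11 higher within the 4 slides. Falls were found for miR-129-2-3p (-0.25, adjusted p = 0.0415), miR-466b-3p (fitted difference -0.42, with 3 of 4 LIF arrays at the floor, adjusted p = 0.0253) and miR-129-1-3p (-0.55, adjusted p = 0.0276). With slide as a block 12 miRNAs rose and 14 fell, and over all probes 1 rose and 0 fell. Only miR-351-3p passed without each array in turn. Without control 1 h replicate 1 or 4, or LIF 1 h replicate 1, 2 or 3, it was the 1 call left, miR-129-2-3p having an adjusted p of 0.300 without control 1 h replicate 1, whereas 9 calls were made without control 1 h replicate 2.

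EPO+LIF for 1 h raised miR-351-3p 1.51-fold to -3.66 ± 0.05 (n = 4; 0.60 ± 0.08, adjusted p = 1.02e-05), by 0.41 to 0.83 within slides. miR-129-2-3p (-0.25, adjusted p = 0.032), miR-181a-1-3p (-0.33, adjusted p = 0.032) and miR-129-1-3p (-0.59, adjusted p = 0.018) fell. The remaining call, miR-466b-3p (fitted difference -0.37 ± 0.10, with 2 of 4 EPO+LIF arrays at the floor, adjusted p = 0.0354), lies outside the naming rule and was chosen after its values were seen. With slide as a block 2 miRNAs rose and 16 fell, and over all probes 1 rose and 0 fell. The number of calls was 1 without EPO+LIF 1 h replicate 1, 2 without control 1 h replicate 1, and 3 without control 1 h replicate 4 or EPO+LIF 1 h replicate 2, 3 or 4; miR-181a-1-3p had an adjusted p of 0.186 without EPO+LIF 1 h replicate 1.

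At 20 h, EPO alone changed 1 miRNA in the fit without a block. miR-34a-5p, a target of p53, rose to -4.48 ± 0.18 and was detected on 4 of 4 EPO arrays, while control arrays all lay at the floor and 1 of 4 detected it (fitted difference 0.22, with 1 of 4 EPO arrays also at the floor, adjusted p = 0.00296). On slide 1 both groups lay at the floor, and within the 3 others it was at least 0.19 higher. miR-34a-5p also lay at the floor on every undifferentiated and 1 h array and on every LIF and LIFlow array at 20 h. Its adjusted p therefore leans on groups that show no spread. miR-338-3p was 0.06 ± 0.19 with EPO against -0.36 ± 0.13 in controls (n = 4 each). Its difference of 0.42 ± 0.14 had an adjusted p of 0.138, or 2.06e-09 with slide as a block, and was 0.37 to 0.50 within the 4 slides. With that block 7 miRNAs rose and 16 fell, among them miR-138-5p (0.27, adjusted p = 0.0184), miR-17-5p (-0.20, adjusted p = 0.00507) and miR-92a-3p (-0.20, adjusted p = 0.00583). There were 3 calls without EPO 20 h replicate 2 and 2 without replicate 4.

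Among the lists at 20 h of EPO, the 14 members of the miR-17 clusters were all lower than in controls, with a median of -0.13 that was -0.05, -0.08 and -0.04 in the other scalings (0 called, 1 fallen adjusted over the list alone, adjusted p = 0.00956, and 0.0477 with an estimated correlation). That call ended when arrays were scaled over all probes (adjusted p = 0.225), in the scanner software's total signal (0.0756) and without EPO 20 h replicate 2 (0.265), the direction of the test turned when every miRNA was tested (adjusted p = 0.0101), and the median was -0.08 without control 20 h replicate 2. With array brightness as a covariate the list's median was -0.07 and the call stayed (adjusted p = 0.00257). The median of all miRNAs detected on all arrays was itself -0.06 in this comparison, so a part of the list's shift was shared by other miRNAs. In the other scalings that median was 0.009, -0.003 and 0.034. Of 4 oligodendrocyte differentiation miRNAs 0 were called and 1, miR-338-3p, rose adjusted over the list alone (median 0.12, adjusted p = 0.0231, but adjusted p = 0.0505 with an estimated correlation). This call also ended without EPO 20 h replicate 1 (0.128), 3 (0.0525) or 4 (0.0884) and without control 20 h replicate 2 (median 0.06, adjusted p = 0.199), with quantile normalization (0.101), in the authors' values (0.118), with the lower floor (0.0606) and with array brightness (0.353), and its median was -0.02 with normexp correction. It ended as well in the total signal (0.133), with every miRNA tested (0.0663) and among miRNAs detected on all arrays (median -0.03, 0.101). In the hypoxia and p53 list miR-34a-5p was the 1 member that rose of 5 (median 0.01, adjusted p = 0.0102, but adjusted p = 0.304 with an estimated correlation and 0.0973 with slide as a block). Its median had no settled sign, at -0.08 without EPO 20 h replicate 2 (adjusted p = 0.167), -0.02 without control 20 h replicate 1, 3 or 4, 0.05 without EPO 20 h replicate 1, 3 or 4 and 0.11 without control 20 h replicate 2. It was -0.01 with the lower floor and -0.09 with normexp correction, where the call ended (0.419), as it did with array brightness (0.0779), slide and row as blocks (0.0972) and without slides 2 and 4 (0.145).

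LIFlow for 20 h raised miR-455-3p, which lies in an intron of a collagen gene, from -4.69 ± 0.02 (n = 4) to -3.93 ± 0.02 (n = 3), at least 1.69-fold (0.76 ± 0.06, adjusted p = 1.05e-11). Control arrays all detected it, 3 of 4 with values at the floor. Its other arm, miR-455-5p, was undetected in controls and at least 1.07-fold higher (adjusted p = 0.0114). miR-27a-3p rose from -0.89 ± 0.12 to -0.56 ± 0.04 (0.33 ± 0.07, adjusted p = 0.00415), and miR-210-3p (0.63 ± 0.15, adjusted p = 0.0114), miR-140-5p (0.53 ± 0.15, adjusted p = 0.0398) and miR-503-5p (0.43 ± 0.12, adjusted p = 0.0398) rose as well. miR-129-2-3p fell by 0.40 (adjusted p = 0.000353). The block by slide gave 13 rises and 16 falls. Scaling over all probes gave 15 rises and 0 falls and the authors' values 6 and 0, and the fall of miR-129-2-3p ended there (-0.17, adjusted p = 0.465, and -0.30, adjusted p = 0.183). On the 1 shared slide the differences were at least 0.77 for miR-455-3p, 0.74 for miR-210-3p, 0.29 for miR-27a-3p and -0.42 for miR-129-2-3p. Of the 7 calls, 3 were left without LIFlow 20 h replicate 1, where miR-210-3p and miR-140-5p had an adjusted p of 0.235, miR-503-5p of 0.270 and miR-455-5p of 0.244, and 4 without control 20 h replicate 4.

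LIF at 10 ng/ml for 20 h raised miR-455-3p at least 2.30-fold to -3.49 ± 0.02 (n = 3; 1.20 ± 0.06, adjusted p = 4.31e-17) and miR-455-5p at least 1.32-fold (adjusted p = 6.12e-11). miR-503-5p, which had fallen in controls, was 1.75-fold higher with LIF than in controls at 20 h (0.80 ± 0.12, adjusted p = 1.35e-05). miR-27a-3p rose 1.47-fold (0.55 ± 0.07, adjusted p = 6.31e-07), and miR-140-5p (0.65, adjusted p = 0.00427), miR-140-3p (0.47, adjusted p = 0.0104), miR-351-5p (0.43, adjusted p = 0.00111), miR-210-3p (0.51, adjusted p = 0.0385) and miR-872-5p (0.24) rose too. miR-129-2-3p (-0.35, adjusted p = 0.0011), miR-19b-1-5p (-0.27), miR-20b-5p (-0.25) and miR-30a-5p (-0.11) fell. Of 14 members of the miR-17 clusters 1 fell (median -0.14, adjusted p = 0.0801). These were 9 rises and 4 falls, against 20 and 23 with slide as a block. The falls depended on the scaling, with 12 rises and 0 falls over all probes, 10 and 1 with quantile normalization and 7 and 0 in the authors' values. Within the 3 shared slides miR-455-3p was at least 1.16 higher, miR-503-5p 0.65 to 0.89, miR-27a-3p 0.52 to 0.61 and miR-210-3p 0.18 to 0.59. Without LIF 20 h replicate 1 there were 8 calls, and miR-140-3p (adjusted p = 0.0902), miR-872-5p (0.0639), miR-20b-5p (0.186) and miR-30a-5p (0.146) were no longer among them; miR-210-3p ended at 0.230 without LIF 20 h replicate 2 and miR-19b-1-5p at 0.145 without control 20 h replicate 4. miR-351-3p, at the floor on every array of both groups here, was 1.16 higher in the scanner software's total signal and 0.52 higher with the lower floor.

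EPO+LIF for 20 h gave 14 rises and 10 falls, or 27 and 42 with slide as a block. The split was 11 and 2 over all probes, 19 and 6 with quantile normalization and 16 and 7 in the authors' values. miR-455-3p rose at least 2.63-fold to -3.30 ± 0.07 (n = 4; 1.40 ± 0.05, adjusted p = 7.01e-20), and miR-455-5p at least 1.53-fold (adjusted p = 4.81e-16). miR-503-5p rose 2.13-fold to -0.71 ± 0.15 (1.09 ± 0.11, adjusted p = 6.69e-09), with its neighbours miR-351-5p (0.49) and miR-322-5p (0.34, adjusted p = 0.00892). miR-27a-3p was -0.34 ± 0.05 against -0.89 ± 0.12 in controls (0.54 ± 0.06, adjusted p = 1.29e-07), and miR-23a-3p of the same primary transcript rose by 0.27. Other rises were miR-210-3p (0.68, adjusted p = 0.000961), miR-140-5p (0.47), miR-22-3p (0.43, adjusted p = 0.0484), miR-152-3p (0.34) and miR-125b-5p (0.30).

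The falls with EPO+LIF at 20 h included miR-129-2-3p, from -2.54 ± 0.08 to -2.98 ± 0.09 (n = 4 each; -0.44, adjusted p = 8.64e-06), miR-129-1-3p (-0.50), miR-19b-1-5p (-0.34), miR-6216 (-0.28) and miR-378b (-0.24). All 14 tested members of the miR-17 clusters were lower, in the median by -0.26 and by -0.19, -0.14 and -0.21 in the other scalings. Of these 4 fell, 5 adjusted over the list alone, with -0.28 for miR-20b-5p, -0.25 for miR-19a-3p, -0.25 for miR-19b-3p and -0.15 for miR-93-5p. The list passed (adjusted p = 0.0037, and 0.0254 with an estimated correlation), but not when arrays were scaled over all probes (0.0896) or every miRNA was tested (0.683). With array brightness as a covariate its median was -0.20 and the call stayed (adjusted p = 3.16e-05). The median of all miRNAs detected on all arrays was itself -0.08 in this comparison. Within the 4 slides miR-455-3p was at least 1.34 higher, miR-503-5p 1.05 to 1.18, miR-27a-3p 0.44 to 0.68 and miR-210-3p 0.25 to 1.07, and miR-129-2-3p was -0.46 to -0.42. Of 22 named calls, 15 passed without each array in turn. Those that ended included miR-22-3p (adjusted p = 0.150) and miR-140-5p (0.116) without control 20 h replicate 3, miR-19b-3p (0.146) without control 20 h replicate 2, miR-129-1-3p (0.0524) and miR-6216 (0.0503) without control 20 h replicate 4, miR-19a-3p (0.172) without EPO+LIF 20 h replicate 2 and miR-23a-3p (0.0987) without EPO+LIF 20 h replicate 3.

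**Figure D1:**
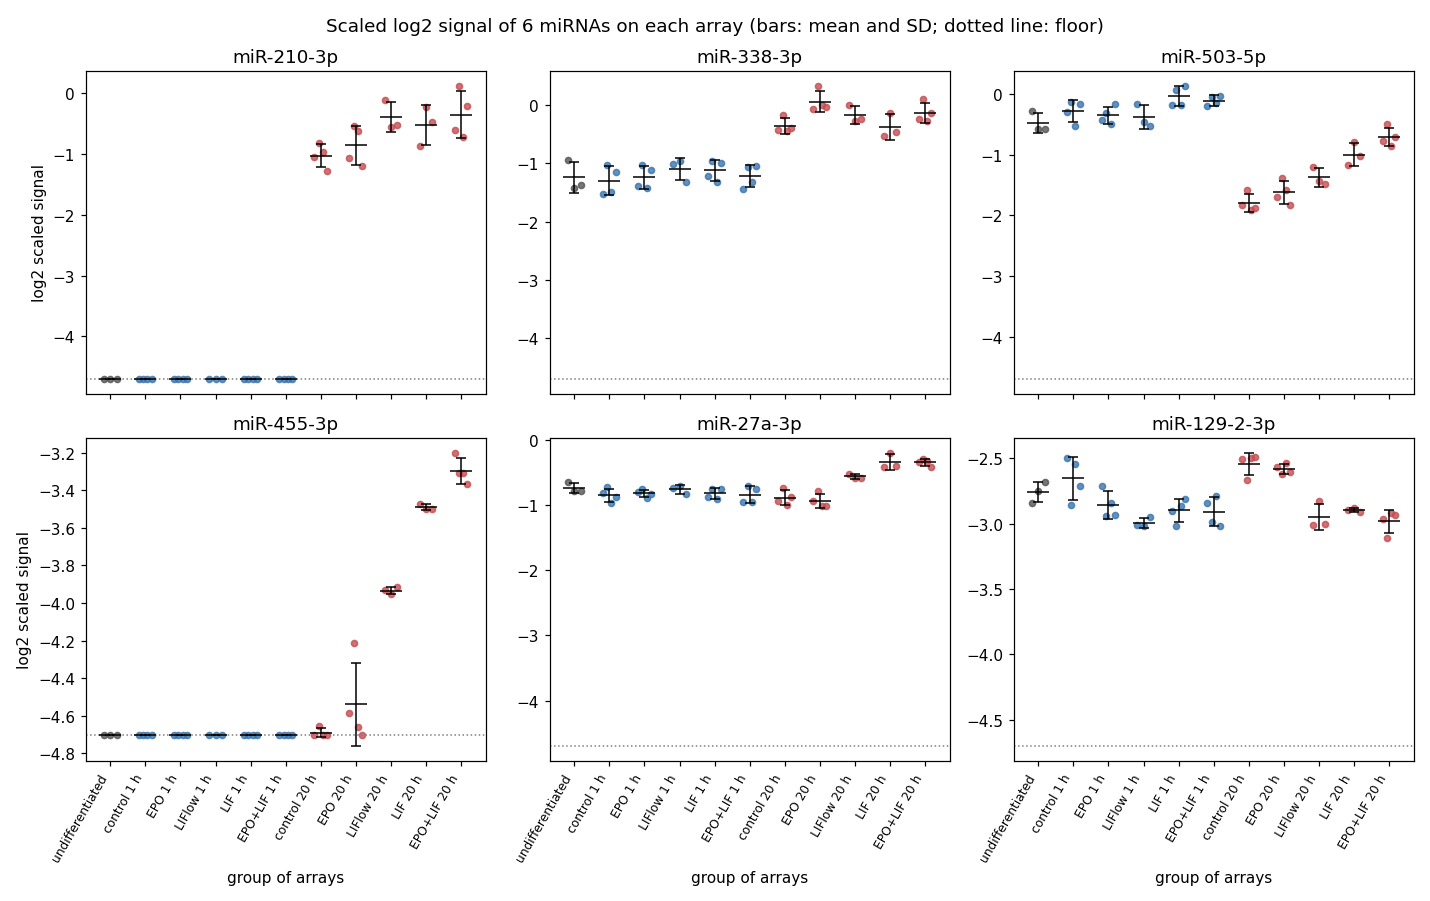
Scaled signal (log2) of 6 miRNAs on each of the 40 arrays, by group, with bars for the mean and SD of each group and a dotted line at the floor of -4.70. miR-210-3p lies at the floor in undifferentiated cells and at 1 h and averages -1.03 in controls at 20 h, and miR-455-3p averages -4.69 in controls at 20 h, -3.93 with LIFlow, -3.49 with LIF and -3.30 with EPO+LIF.

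Whether the LIF doses of 0.2 and 10 ng/ml differed was tested directly. At 1 h only miR-351-3p was higher with the higher dose (0.62 ± 0.09, adjusted p = 1.8e-05; 0.81 on the 1 shared slide), and in the authors' values 0 miRNAs rose and 1 fell. At 20 h miR-455-3p was higher by 0.44 ± 0.06 and miR-455-5p by 0.30 ± 0.04 (adjusted p = 4.57e-06 each). miR-503-5p (0.38, adjusted p = 0.278), miR-351-5p (0.29, adjusted p = 0.261) and miR-27a-3p (0.23, adjusted p = 0.261) did not pass at 20 h. With slide as a block there were 4 rises and 1 fall at 1 h and 7 rises and 1 fall at 20 h. No slide held both doses at 20 h, and with normexp background correction miR-351-3p at 1 h was -0.41.

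What EPO added to LIF was small. At 20 h miR-455-5p was higher with EPO+LIF than with LIF (0.21 ± 0.04, adjusted p = 0.00163; 0.08 to 0.34 within slides), which was the only call, and miR-455-3p stood at 0.19 (adjusted p = 0.188). With slide as a block 5 miRNAs rose and 1 fell, among them miR-503-5p (0.32, adjusted p = 0.00162) and miR-338-3p (0.27, adjusted p = 8.28e-05). The miR-17 clusters had a median of -0.06 with 1 of 14 higher and 0 called, also 0 adjusted over the list alone (adjusted p = 0.0212, but adjusted p = 0.0822 with an estimated correlation). That call ended without EPO+LIF 20 h replicate 2 (0.326) and without LIF 20 h replicate 1 (0.132) or 3 (0.290), and the median was -0.02 without LIF 20 h replicate 2, -0.09 without EPO+LIF 20 h replicate 1 and -0.11 without EPO+LIF 20 h replicate 3. It ended over all probes (median -0.10, 0.258), with quantile normalization (median -0.03, 0.313) and with the replicate number as a block (median -0.04, 0.0747), and the direction of the test turned when every miRNA was tested (adjusted p = 0.00132). The median was -0.03 without slides 2 and 4 and -0.11 in the total signal. At 1 h limma made 0 calls, with 6 miRNAs at an unadjusted p under 0.05 and 0 rises and 3 falls with slide as a block. These included miR-351-3p (-0.31, adjusted p = 0.108, or 0.0279 with the block) and miR-674-3p (-0.33, adjusted p = 0.108, or 0.0108 with it). Without LIF 20 h replicate 3 the call of miR-455-5p ended (adjusted p = 0.0744), and 2 calls were made at 1 h without LIF 1 h replicate 1.

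What LIF added to EPO was larger. At 1 h EPO+LIF exceeded EPO in miR-351-3p (0.70 ± 0.08, adjusted p = 3.44e-07; 0.57 to 0.90 within the 4 slides), the only call. At 20 h the rises were miR-455-3p (at least 1.24, adjusted p = 1.8e-18), miR-503-5p (0.91, adjusted p = 2.64e-07), miR-140-5p (0.68), miR-455-5p (0.65, with 3 of 4 EPO arrays at the floor), miR-27a-3p (0.59, adjusted p = 2.51e-08), miR-351-5p (0.57), miR-140-3p (0.56), miR-210-3p (0.50), miR-322-3p (0.46) and miR-23a-3p (0.33). miR-34a-5p (-0.20, with 3 of 4 EPO+LIF arrays and 1 of 4 EPO arrays at the floor, adjusted p = 0.00105) and miR-129-2-3p (-0.40, adjusted p = 4.23e-05) were lower. Counts at 20 h were 13 rises and 2 falls, against 26 and 19 with slide as a block, and at 1 h the block gave 2 rises and 2 falls, the title letter as a block 2 calls in all. The authors' values gave 4 rises and 5 falls at 20 h and 0 and 3 at 1 h. Within slides miR-210-3p ranged from -0.10 to 0.99 and its call ended without EPO+LIF 20 h replicate 2 (adjusted p = 0.179), as that of miR-322-3p did without EPO 20 h replicate 2 (0.108); miR-351-3p at 1 h was -0.26 with normexp background correction.

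Whether EPO and LIF acted additively on the log2 scale was tested as an interaction. At both times 0 miRNAs passed by limma, with and without slide as a block, and 4 at 1 h and 3 at 20 h had an unadjusted p under 0.05. The lowest p-values were those of miR-466b-3p at 1 h (0.36, adjusted p = 1) and of miR-455-5p (0.19, adjusted p = 0.243) and miR-34a-5p (-0.20, adjusted p = 0.336) at 20 h. At 1 h the list of miR-17 clusters passed (median -0.10, adjusted p = 0.0014, and 0.0136 with an estimated correlation), but not with quantile normalization (0.0659) or in the authors' values (0.0624), and the direction of the test turned with normexp correction (median -0.03, adjusted p = 0.0885). At 20 h the hypoxia and p53 list passed (median -0.04, adjusted p = 8.54e-04, but adjusted p = 0.305 with an estimated correlation). Its median had no settled sign, at 0.05 without LIF 20 h replicate 2 (adjusted p = 0.0974), 0.03 without EPO 20 h replicate 2, 0.02 without EPO+LIF 20 h replicate 1, 0.02 without slides 2 and 4 and 0.05 with normexp correction (0.790), and as low as -0.18 without LIF 20 h replicate 1 and -0.14 over all probes. The call ended with every miRNA tested (adjusted p = 0.974). In both lists 0 members were called. Without EPO 20 h replicate 2 there were 3 calls at 20 h and without replicate 1 there was 1.

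The last comparisons asked whether a treatment's effect differed between 1 h and 20 h. For LIF the difference passed for miR-455-3p (1.20, adjusted p = 2e-13), miR-455-5p (0.46, adjusted p = 8.46e-08), miR-27a-3p (0.53, adjusted p = 0.000287), miR-351-5p (0.43, adjusted p = 0.0407), let-7f-5p (-0.18, adjusted p = 0.0487) and miR-351-3p (-0.90, adjusted p = 1.92e-06). For EPO+LIF it passed for miR-455-3p (1.40, adjusted p = 1.18e-15), miR-503-5p (0.92, adjusted p = 0.000139), miR-455-5p (0.67), miR-351-5p (0.59, adjusted p = 0.00064), miR-27a-3p (0.54, adjusted p = 0.000139), miR-326-3p (0.29, adjusted p = 0.00465) and miR-351-3p (-0.50, adjusted p = 0.00465). For LIFlow only miR-455-3p passed (0.76 ± 0.08, adjusted p = 4.44e-08). For EPO limma made 0 calls, with 6 miRNAs at an unadjusted p under 0.05, and miR-34a-5p (0.22, adjusted p = 0.194) had the lowest p. Both arms of miR-455 lay at the floor on every 1 h array, so these differences equal the changes at 20 h. The same holds for miR-326-3p with EPO+LIF, for which 1 of 4 control arrays at 20 h also lay at the floor. With slide as a block the counts were 3 rises and 8 falls for EPO, 8 and 5 for LIFlow, 11 and 18 for LIF and 24 and 15 for EPO+LIF.

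The interaction of miR-351-3p rests on the floor, where most of its 20 h values lay. For LIF it was 0.21 in the scanner software's total signal and 2.70 in the authors' values, and for EPO+LIF it was 0.84 and 3.32 there and 0.29 with the lower floor. Without LIF 20 h replicate 2 the calls of miR-351-5p and let-7f-5p with LIF ended (adjusted p = 0.219 each), and without EPO 20 h replicate 1 there was 1 call for EPO; miR-455-3p with LIFlow was -0.50 with normexp background correction. The miR-17 clusters were lower in all 4 interactions with time, with medians of -0.18 for EPO (adjusted p = 5.85e-05), -0.19 for LIFlow (3.96e-04), -0.20 for LIF (9.02e-04) and -0.24 for EPO+LIF (2.05e-04). The LIFlow call ended without LIFlow 1 h replicate 3 (median -0.12, adjusted p = 0.0976), and the median was -0.12 for EPO without control 20 h replicate 2 and -0.11 with array brightness, -0.43 for EPO+LIF over all probes and -0.13 for LIF without LIF 20 h replicate 1. With normexp correction the direction of the test turned and the call ended for EPO (median -0.08, adjusted p = 0.545) and LIFlow (median -0.01, adjusted p = 0.0602). With an estimated correlation their adjusted p was 0.002, 0.0062, 0.0103 and 0.00416. These 4 tests share the 8 control arrays and are not independent of one another.

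Of the lists for other cell types, only the neuron list had at least 3 tested members, and limma called it in 0 comparisons. Of the members, 1 was tested for astrocyte, 2 for microglia and blood, 0 for muscle, 1 for endothelium and fibroblast and 0 for epithelium. The neuron list, which holds miR-129-2-3p, had a median at 20 h of -0.36 with LIFlow (adjusted p = 0.246), -0.35 with LIF (adjusted p = 0.186) and -0.44 with EPO+LIF (adjusted p = 0.148), and passed in 5 comparisons with slide as a block. From 1 h to 20 h in controls its median was 0.11 (adjusted p = 0.869).

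The named miRNAs lie at these places in rn4, as the scanner files give them. miR-210-3p is on chromosome 1 from 201415728 to 201415742, miR-338-3p on chromosome 10 from 109427033 to 109427054, and miR-503-5p on chromosome X from 139999883 to 139999897. miR-351-3p is on chromosome X from 139999194 to 139999205, miR-455-3p on chromosome 5 from 80239900 to 80239915, and miR-34a-5p on chromosome 5 from 167187919 to 167187937. miR-27a-3p is on chromosome 19 from 25638638 to 25638653, miR-140-5p on chromosome 19 from 37422727 to 37422746, and miR-129-2-3p on chromosome 3 from 78648995 to 78649012. miR-138-5p has places on chromosomes 8 and 19.

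**Figure D2:**
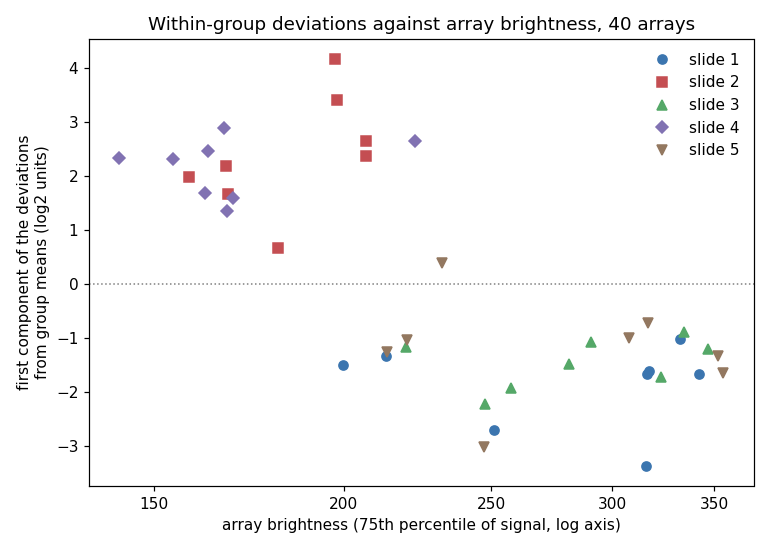
First component of the arrays' deviations from their group means (vertical axis, log2 units) against array brightness (75th percentile of signal, log axis), 1 point per array, marked by slide. Arrays of slides 2 and 4 average 2.39 and 2.16 on the component, and those of slides 1, 3 and 5 average -1.87, -1.47 and -1.21.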

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

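In this part the tests of the 3 weighed patterns, the grouping of miRNAs by genomic position and the other splits of the samples, with the choice of which of them compare, were chosen only after the result was seen, while the interactions with time and the search for arrays far from their group were planned.

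Of at most 112 groups of 4 arrays, 8 had 1 array far from the other 3, 7 of them on slide 2. Groups with all 4 arrays at the floor, as for miR-455-3p in controls at 1 h, have no spread and were passed over. Fewer than 112 were therefore examined. Chance gives about 1 in 20 for measured values, but for 4 of the 8 the other 3 arrays lay at the floor, where any value above it stands apart by construction, so that rate does not apply to them. With EPO at 20 h, replicate 2 stood at 0.34 for miR-338-3p where the others averaged -0.03, at -2.38 for miR-140-5p where they averaged -2.99, and at -4.62 for miR-455-5p with the others at the floor of -4.70. With EPO+LIF at 20 h, replicate 2 stood at -4.33 for miR-351-3p and at -4.62 for miR-34a-5p, with the others at the floor. In control 20 h, replicate 2 stood at -4.65 for miR-455-3p, with the others at the floor, and at -2.67 for miR-129-2-3p where they averaged -2.50. With EPO at 1 h, replicate 3 stood at -4.55 for miR-351-3p where the others averaged -4.30.

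The effects of LIF and EPO+LIF differed between 1 h and 20 h for several miRNAs, by the test of the interaction. For LIF the log2 difference was 1.20 for miR-455-3p, 0.46 for miR-455-5p, 0.53 for miR-27a-3p, 0.43 for miR-351-5p, -0.18 for let-7f-5p and -0.90 for miR-351-3p. For EPO+LIF it was 1.40 for miR-455-3p, 0.67 for miR-455-5p, 0.92 for miR-503-5p, 0.59 for miR-351-5p, 0.54 for miR-27a-3p, 0.29 for miR-326-3p and -0.50 for miR-351-3p. For LIFlow it was 0.76 for miR-455-3p. The values of miR-351-3p rest on the floor, and its sign turned in other settings. The calls of miR-351-5p and let-7f-5p for LIF ended without LIF 20 h replicate 2.

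Arrays on the same slide deviated from their group means together, along a first component that held 78.3% of the variance within groups. Pairs of arrays of different groups and letters correlated at 0.704 on the same slide, which argues against a shared culture behind each letter as the whole cause. With array brightness as a covariate the same-slide correlation was 0.00275, so hybridisation or scanning of a slide, acting through brightness, may be the source. Since brightness itself differed between slides, this cannot tell it from another difference between them. The component changed by -6.32 ± 0.33 (standard error) per unit of log2 brightness, and by -3.48 ± 0.62 with slide also in the model. Brightness averaged 185 and 169 on slides 2 and 4 and 286, 288 and 280 on slides 1, 3 and 5. A contribution of the culture stays open, since slides 1, 2 and 3 held 1 letter each and pairs on different slides decide nothing (-0.0974 with the same letter, -0.149 with different letters), and no other biological explanation was tested.

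Of the 34 miRNAs that fell from 1 h to 20 h in controls, 21 were dimmer than the median level of tested miRNAs, and their median change was -0.46. Arrays at 20 h were brighter than at 1 h by 0.36 ± 0.05 on the log2 scale, or 1.29-fold, and with array brightness as a covariate 63.1% of the median change was left (-0.29), so a part of these falls may follow brightness, which is partly confounded with time. Brightness as the whole cause is argued against, since 76.2% of them, 16 of 21, were still called lower with it, as were all 13 other falls. Slide row is argued against as well, with 99.0% of the change left with slide and slide row as blocks. A change in the cells with time in differentiation medium stays open and was not tested apart from these.

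On the X chromosome, from 139994969 to 140000240 in rn4, lie miR-322-3p, miR-322-5p, miR-351-3p, miR-351-5p, miR-450a-5p and miR-503-5p, of which 5 of 6 were lower in control 20 h than in control 1 h (median -0.54; -0.32, -0.36 and -0.74 in the other scalings) and 6 of 6 higher with EPO+LIF at 20 h (median 0.35; 0.41, 0.32 and 0.49), which for miR-351-3p rests on replicate 2 of EPO+LIF alone, with the 3 others and all 4 controls at the floor. Camera gave adjusted p of 0.00396 and 2.06e-04, and of 0.0168 and 0.00122 with an estimated correlation. Brightness (88.1% of the fall and 96.1% of the rise left) and, for the rise alone, scaling (at least 92.5% left) are argued against as causes. A row effect alike on all slides is argued against too (95.0% of the fall left), though row and time cannot be told apart on slides 1, 2 and 3. Scaling stays open for the fall, of which 59.6% was left over all probes. A shared primary transcript that falls in differentiating cells and is kept higher by the cytokines is a candidate explanation, which the smaller share of members in the stated direction, 83.3%, left undecided. The treatment itself stays among the open explanations.

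Other splits of the same samples into groups of the same sizes were fitted for each comparison, all of them where they were few and 100 drawn for the interactions. In the interactions with time, only members of a pair changed places at a time where letters pair the samples, and for EPO and EPO+LIF at both times only arrays on 1 slide. For control 20 h against undifferentiated cells, only the real split of 35 called as many (45 calls, at most 34 in another split). That is the smallest share these splits can give. It was not adjusted for the 23 comparisons, and the splits were chosen after the result was seen. Chance therefore stays open there. It could not be excluded for control 1 h against undifferentiated cells (4 and 12), LIFlow 1 h (3 and 4), LIF against LIFlow at 1 h (1 and 2), LIFlow by time (1 and 14, with 23 of 100 splits as large), LIF by time (6 and 17, with 10 of 100) or EPO+LIF by time (7 and 23, with 10 of 100). For EPO+LIF by time the outcome depended on the draw, since 1 of 100 was as large, with a highest other of 1, when only the letters at 1 h were kept. In draws that ignored the letters the highest were 27 for EPO+LIF by time, 6 for LIFlow and 103 for LIF, and 4, 10 and 7 of 100 were as large.

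Where letters pair the samples, only the 8 splits that part as many pairs as the real one compare with it, too few for a share under 0.05. Their real and highest other counts were 60 and 8 for control 20 h against control 1 h, 4 and 1 for LIF 1 h, 5 and 1 for EPO+LIF 1 h, 7 and 1 for LIFlow 20 h and 13 and 4 for LIF 20 h. They were 1 and 0 for EPO+LIF against EPO at 1 h, 15 and 3 at 20 h, and 1 and 1 for EPO+LIF against LIF at 20 h. The splits for LIF against LIFlow at 20 h (2 and 1) are also too few. Letters do not pair EPO 20 h or EPO+LIF 20 h with control 20 h, but each array shares its slide with 1 control, and the 8 splits that part these pairs are too few as well (1 and 1, with 2 of 8 as large, and 24 and 0). Over all 35 splits the highest other counts were 1 and 2, with 5 and 1 as large. Where the real count was 0, each split gives as many by construction, 100 of 100 for the interactions, so the splits say nothing about chance. This concerns EPO 1 h, EPO+LIF against LIF at 1 h, EPO by LIF at both times (81 and 8 in the highest other split) and EPO by time (1).

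Splits that call many times the real number point to a structure of the samples. Those that keep pairs together mostly differ from the real one in that they set slides against each other, and they reached 39 calls for control 20 h against control 1 h, 6 for LIFlow 20 h, 13 for LIF 20 h, as many as the real one, and 2 and 8 for EPO+LIF against LIF and against EPO at 20 h. The highest at 1 h, with 44 calls for EPO, 69 for LIF, 19 for EPO+LIF, 97 for EPO+LIF against LIF and 65 for EPO+LIF against EPO, separate slides 2 and 4 from slides 1 and 3. The real comparisons with slide as a block gave 1, 26, 18, 3 and 4 calls.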

How the results depend on the processing

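Of the tests in this part, the fits with slide and slide row, with array brightness, and without slides 2 and 4, the scaling summary and the genomic groups were chosen after seeing the data, and the others were planned. Of the 148 calls of named miRNAs, 148 stayed past the threshold in the same direction with slide as a block and 148 with the title letter as a block. The number was 147 with the replicate number as a block and 147 with slide and slide row, 145 with array brightness, 140 without slides 2 and 4, and 128 with the floor at 50% of its value. It was 110 with quantile normalization, 108 with every miRNA tested, 103 with the scanner software's total signal, 102 with the percentile over all probes, 86 in the authors' values and 31 with normexp background correction. Of the 106 named calls among miRNAs detected on all 40 arrays, 95 stayed when only those were tested. Across omissions of single arrays 1051 of 1228 stayed, and 102 of the 148 stayed in each. Where a cause is not given, the cause was not tested. The signal over background limits all of this, since between 16.7% and 23.4% of spots per array were well above background and values near the floor carry no order.

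With slide as a block the counts were 23 for control 1 h against undifferentiated cells, 78 for control 20 h against undifferentiated cells and 103 for control 20 h against control 1 h. Against controls they were 1 for EPO, 14 for LIFlow, 26 for LIF and 18 for EPO+LIF at 1 h, and 23, 29, 43 and 69 at 20 h. LIF against LIFlow gave 5 at 1 h and 8 at 20 h, EPO+LIF against LIF gave 3 and 6, and EPO+LIF against EPO gave 4 and 45. By time they were 11 for EPO, 13 for LIFlow, 29 for LIF and 39 for EPO+LIF. There were 28 list calls and 5 for cell type lists.

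Slide and slide row together gave 18 for control 1 h and 77 for control 20 h against undifferentiated cells and 92 for control 20 h against control 1 h. Against controls they gave 10 for LIFlow, 27 for LIF and 15 for EPO+LIF at 1 h, and 23 for EPO, 29 for LIFlow, 46 for LIF and 66 for EPO+LIF at 20 h. LIF against LIFlow gave 5 and 7, EPO+LIF against LIF 3 and 6, and EPO+LIF against EPO 4 and 44 at the earlier and later time. By time the counts were 10 for EPO, 10 for LIFlow, 27 for LIF and 35 for EPO+LIF, with 29 list calls and 5 for cell type lists.

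Array brightness as a covariate gave 30 for control 1 h and 79 for control 20 h against undifferentiated cells. Against controls it gave 12 for LIFlow, 11 for LIF and 19 for EPO+LIF at 1 h, and 20 for EPO, 33 for LIFlow, 32 for LIF and 48 for EPO+LIF at 20 h. LIF against LIFlow gave 4 and 5, EPO+LIF against LIF 3 and 5, and EPO+LIF against EPO 6 and 31. By time there were 10 for EPO, 8 for LIFlow, 21 for LIF and 27 for EPO+LIF, with 23 list calls and 1 for cell type lists. With it miR-542-3p in control 20 h vs undifferentiated turned to -0.23 and miR-29a-3p in control 20 h vs control 1 h to 0.14.

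Without slides 2 and 4 there were 14 calls for control 1 h and 74 for control 20 h against undifferentiated cells and 94 for control 20 h against control 1 h. Against controls there were 2 for EPO, 10 for LIFlow, 27 for LIF and 27 for EPO+LIF at 1 h, and 25, 20, 54 and 55 at 20 h. LIF against LIFlow gave 2 and 5, EPO+LIF against LIF gave 5 at 20 h, and EPO+LIF against EPO gave 2 and 37. EPO by LIF gave 2 at 1 h and 1 at 20 h. By time there were 5 for EPO, 9 for LIFlow, 29 for LIF and 26 for EPO+LIF, with 24 list calls and 5 for cell type lists.

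Normexp correction left 0 calls for control 1 h against undifferentiated cells, for LIFlow, LIF and EPO+LIF at 1 h, for EPO and LIFlow at 20 h, for LIF against LIFlow at both times, for EPO+LIF against EPO at 1 h and against LIF at 20 h, and for LIFlow, LIF and EPO+LIF by time. It left 16 for control 20 h against undifferentiated cells, 16 for control 20 h against control 1 h, and 2 each for LIF 20 h, EPO+LIF 20 h and EPO+LIF against EPO at 20 h, and made 40 list calls. It adds 50 to each spot before scaling, which shrinks differences between dim values by construction; why directions turned was not tested. In control 20 h vs undifferentiated it turned miR-598-3p to -0.12, miR-30c-5p to -0.0155, miR-34c-5p to -0.16 and miR-129-2-3p to -0.0852. In control 20 h vs control 1 h it turned miR-598-3p to -0.12, miR-30e-5p to -0.0211, miR-30a-5p to -0.0773 and miR-34c-5p to -0.16. At LIFlow 1 h miR-129-2-3p was 0.32 and miR-466b-3p 0.50, at LIF 20 h miR-872-5p was -0.0259, and at EPO+LIF 20 h miR-152-3p was -0.0092. For miR-351-3p LIF against LIFlow at 1 h was -0.41 and EPO+LIF against EPO at 1 h -0.26, and miR-455-3p in LIFlow by time was -0.50. The list test of the miR-17 clusters turned for EPO 1 h (median -0.0223), EPO by LIF at 1 h (-0.0297), EPO by time (-0.084) and LIFlow by time (-0.0123).

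Testing only miRNAs detected on all 40 arrays left 0 calls for control 1 h against undifferentiated cells, LIF 1 h, EPO 20 h, LIF against LIFlow at both times, EPO+LIF against EPO at 1 h, EPO+LIF against LIF at 20 h and LIFlow by time. It left 1 for LIFlow 1 h and 1 for LIF by time, 2 for LIFlow 20 h, 3 for EPO+LIF 1 h and 3 for EPO+LIF by time, 7 for LIF 20 h and 8 for EPO+LIF against EPO at 20 h. It made 24 list calls and 1 for cell type lists. Fewer miRNAs were tested here, and neither arm of miR-455 was among them. Testing every rat miRNA adjusts over more tests. It also brings into the fit the 525 miRNAs detected on no array. Where these lie at the floor they show no spread, which can distort the pooled spread and the list tests. List calls that were gained, ended or turned in this setting are therefore hard to read. Testing every miRNA gave 1 call each for control 1 h against undifferentiated cells, LIF 1 h and EPO+LIF 1 h, 39 for control 20 h against control 1 h, 4 for LIFlow 20 h, 77 list calls and 1 for cell type lists. The test of the miR-17 clusters turned there for EPO 20 h (median -0.13), EPO+LIF 20 h (-0.25) and EPO+LIF against LIF at 20 h (-0.057), while the medians kept their sign. Why it turned was not tested.

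The scanner software's total signal gave 0 for control 1 h against undifferentiated cells and for LIF against LIFlow at 20 h, 1 for EPO+LIF 1 h and for EPO by LIF at 20 h, and 2 for LIF against LIFlow at 1 h. It gave 3 for EPO by time, 4 for EPO 20 h, 5 for LIFlow by time, 8 for LIFlow 1 h, 11 for EPO+LIF by time and 12 for LIFlow 20 h. The lower floor gave 2 for control 1 h against undifferentiated cells and for LIFlow by time, 1 for LIFlow 1 h and for EPO by time, 3 for LIF by time and 0 for LIF against LIFlow at 20 h. Both showed differences of miR-351-3p where the main fit had none, with every array of the compared groups at the floor. These were -0.77 and -0.69 in control 20 h vs undifferentiated and 1.16 and 0.52 at LIF 20 h. In LIF by time miR-351-3p turned to 0.21 in the total signal, and in EPO+LIF by time to 0.84 and 0.29, because its 20 h values lay mostly at the floor.

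The authors' values gave 12 calls for control 1 h and 78 for control 20 h against undifferentiated cells, 1 for LIF 1 h and for EPO by time, 3 for EPO 20 h and for EPO+LIF against EPO at 1 h, 7 for LIF 20 h and 9 for EPO+LIF against EPO at 20 h. They gave 0 for LIF against LIFlow at 20 h, EPO+LIF against LIF at 20 h and LIFlow by time, 24 list calls and 1 for cell type lists. In them let-7a-5p in control 20 h vs undifferentiated was -0.16, miR-181a-5p there -0.00274, miR-30a-5p in control 20 h vs control 1 h -0.0303, and miR-351-3p 2.70 in LIF by time and 3.32 in EPO+LIF by time.

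Scaling over all probes gave 1 for LIF 1 h and for EPO+LIF 1 h, 2 for EPO 20 h, EPO+LIF against LIF at 20 h and EPO by time, 5 for LIFlow by time, 13 for EPO+LIF 20 h and 15 for LIFlow 20 h, and turned miR-384-5p in control 1 h vs undifferentiated to -0.0338. Quantile normalization gave 2 for LIF 1 h, EPO+LIF 1 h, EPO 20 h and LIFlow by time, 1 for LIF against LIFlow at 20 h, EPO+LIF against LIF at 1 h and EPO by time, 4 for EPO+LIF against LIF at 20 h and 11 for EPO+LIF by time. Scaling over all probes moved the median of the miRNAs detected on all arrays by more than 0.1 in 10 of 23 comparisons, at most by 0.23 for EPO+LIF 1 h, the authors' values in 4, at most by 0.21, and quantile normalization in 0. Higher and lower calls then split differently. In control 20 h against control 1 h they were 29 and 16 over all probes and 19 and 64 in the authors' values, and in control 20 h against undifferentiated cells 11 and 22, and 13 and 65. Control 1 h against undifferentiated cells gave 0 and 3 over all probes, 2 and 3 with quantile normalization, and 0 and 12 in the authors' values. EPO+LIF 20 h gave 11 and 2, 19 and 6, and 16 and 7, LIF 20 h 12 and 0, 10 and 1, and 7 and 0, LIFlow 20 h 15 and 0 over all probes and 6 and 0 in the authors' values, and EPO+LIF against EPO at 20 h 9 and 3, 9 and 3, and 4 and 5. At 1 h LIFlow gave 3 and 0, 2 and 1, and 3 and 0, LIF 1 and 0, 1 and 1, and 0 and 1, and EPO+LIF 1 and 0 and, with quantile normalization, 1 and 1. In the authors' values LIF against LIFlow at 1 h gave 0 and 1 and EPO+LIF against EPO at 1 h 0 and 3. LIFlow by time gave 4 and 1 over all probes and 1 and 1 with quantile normalization, LIF by time 4 and 1 with quantile normalization and 4 and 0 in the authors' values, and EPO+LIF by time 5 and 3 over all probes and 8 and 3 with quantile normalization.

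With the title letter as a replicate block the counts were 2 for EPO 20 h, 2 for EPO+LIF against EPO at 1 h, 4 for LIF against LIFlow at 20 h, 12 for EPO+LIF by time and 1 for cell type lists. With the replicate number as a replicate block they were 2, 2 and 13 for EPO 20 h, EPO+LIF against EPO at 1 h and EPO+LIF by time. For camera with an estimated correlation 7 of 14 list calls stayed. Of the 14, 14 stayed with the title letter as a block, 13 with the replicate number and 13 with the lower floor. The number was 11 with slide, with slide and slide row, with array brightness, without slides 2 and 4, over all probes, in the total signal and in the authors' values. It was 9 with quantile normalization and 6 with normexp correction and with every miRNA tested, and 9 of 11 among miRNAs detected on all arrays.

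Leaving out each array in turn gave 1 to 9 calls for control 1 h and 40 to 48 for control 20 h against undifferentiated cells, and 40 to 61 for control 20 h against control 1 h. At 1 h it gave 0 to 1 for EPO, 2 to 7 for LIFlow, 1 to 9 for LIF and 1 to 6 for EPO+LIF, and at 20 h 1 to 3, 3 to 9, 8 to 15 and 19 to 24. LIF against LIFlow stayed at 1 and 2, EPO+LIF against LIF gave 0 to 2 at 1 h and 0 to 1 at 20 h, and EPO+LIF against EPO stayed at 1 at 1 h and gave 13 to 16 at 20 h. EPO by LIF stayed at 0 at 1 h and gave 0 to 3 at 20 h. By time EPO gave 0 to 1, LIFlow stayed at 1, LIF gave 4 to 8 and EPO+LIF 7 to 9. There were 11 to 17 list calls and 0 to 1 for cell type lists, the latter 1 without LIFlow 20 h replicate 1.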

Other observations

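The groups of neighbouring miRNAs described here were formed, and their tests chosen, only after the results were seen; the lists were planned. On chromosome 19, from 25638494 to 25638809 in rn4, miR-23a-3p, miR-27a-3p and miR-24-3p were all higher than in controls at 20 h under each scaling, with medians of 0.24 for LIFlow (adjusted p = 0.00527, and 0.0146 with an estimated correlation), 0.29 for LIF (3.5e-04 and 0.00215) and 0.27 for EPO+LIF (0.00423 and 0.0104). The related group on chromosome 17, from 7351018 to 7351765, with miR-23b-3p, miR-27b-3p and miR-24-3p, was higher in control 20 h than in control 1 h (median 0.51, 3 of 3 called, adjusted p = 0.0019, but adjusted p = 0.106 with an estimated correlation). miR-24-3p has places in both groups and counts in each. On chromosome 15, from 99853794 to 99854509, 8 members of the miR-17 cluster were all lower with EPO+LIF at 20 h, with a median of -0.27, or -0.21, -0.16 and -0.22 in the other scalings (3 called, adjusted p = 0.0108, and 0.0159 with an estimated correlation).

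Many listed miRNAs were not detected, as was true of most rat miRNAs on the array. Of these, 525 were detected on no array and 147 on all 40. Whether any list differed from the array as a whole was not tested, so the counts that follow are descriptive only. Of 29 members of the Dlk1-Dio3 imprinted cluster, which is active in brain, 26 were detected on no array, and of 9 oligodendrocyte differentiation miRNAs 5 were detected on none. In contrast 14 of 15 members of the miR-17 clusters and 9 of 9 of the let-7 family were detected on all arrays. Of the lists for other cell types, 5 of 8 neuron, 5 of 6 astrocyte, 5 of 7 microglia and blood, 2 of 4 muscle, 7 of 8 endothelium and fibroblast, and 7 of 7 epithelium members were detected on no array.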
